A study of Homo sapiens with 6 samples.

How the data were processed

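The series holds 6 RNA sequencing libraries of the human podocyte line HPC, 3 with NC lentivirus and 3 with PRDM16 lentivirus, all in high glucose and with 24 h in their titles. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was captured on oligo(dT) beads and fragmented, and cDNA made from random hexamers was amplified by PCR. Groups and replicate numbers came from the sample titles. The glucose concentration, the promoter and dose of the lentivirus, the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. The genome build is hg38, per the submitters' processing notes.

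For each sample the authors deposited 1 table with a line per gene, holding raw read counts, TPM and FPKM, per the file headers, with the exon coordinates, strand and length of each gene. The deposited counts are whole numbers. The deposited FPKM values were made from the counts, the listed lengths and the library total, and the deposited TPM values sum to 1000000 in each library, as checked on the files. Identifiers are the gene symbol after a fixed prefix. Each table lists 38648 genes. Of these, 4252 lie on scaffolds and alternate haplotypes outside the chromosomes, which hold 0.757% of all counts. There are 2008 genes listed at more than 1 place, with the later listings numbered after the symbol (TCEA3-2). The lines of 7 genes were broken over several lines and were put back together, after which the counts summed to the totals that the FPKM values imply. No mitochondrial genome transcripts were analysed here. Of the listed genes, 36282 (93.9%) had a name in the RefSeq gene table of the reference, which gave the gene type only. Coordinates are those of the deposited tables.

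Totals were between 20147135 and 41280350 counts, so that 3 counts, the floor used for a gene at 0, stand for 0.0727 to 0.149 CPM. Intervals and floors cover counting error only, since PCR copies are not independent molecules. No pair of libraries lay within sampling noise of each other (chi-square per degree of freedom between 9.36 and 61.9), so each library counted as 1 sample. Same-numbered libraries of the 2 groups gave no sign of deviating together (the check is given with the alternatives), and no pairing was used.

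Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust estimation, TMM factors and the default filter on low counts (a minimum count of 10 and a minimum total of 15), which left 15381 genes. The common biological coefficient of variation was 0.146. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by the TMM factors unless they describe markers over all libraries, which are plain CPM. Standard errors of log2 fold changes were taken from the fold change and the F statistic. The fold of PRDM16 is a bound, from the pooled CPM of the PRDM16 group over 3 counts in the NC group. Its exact permutation test used log2 of plain CPM plus 0.1.

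The 45 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with PRDM16 left out. The same test with an estimated correlation, and fry, were alternatives. The lists of mitochondrial genome transcripts (0 tested members) and endothelial markers (4 tested members) were too short. The rule named PRDM16, up to 12 genes per direction with the largest fold change among those that passed with a mean of at least 5 CPM and groups that do not overlap, or the 5 with the smallest p where none passed, the 5 most abundant that passed with a log2 fold change of at least 0.5 in size, and up to 4 members with the smallest p in each list described. For the 5 lower genes the level and the separation of groups were also required, a reading of the rule made after the files were seen. The lists described in the text were chosen from the 45 after the results were seen, with their members named by the rule. Some marker genes are not reported here. Marker genes of cell types were picked from the lists by their role after their levels were seen, as were UCP1 and MECOM.

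GC content is the median over the GENCODE transcripts of each gene name in the reference, matched by current or older symbols, and was found for 13892 of the tested genes (90.3%). For the removal of the length and GC trend, the log2 CPM deviation of each library was regressed on natural splines (5 degrees of freedom each) of log2 length and GC content, and the fitted values entered the model as offsets. Matched lists were drawn 10000 times, each member replaced by 1 of its 50 nearest genes in length, GC content and level, and the share of a median kept was resampled over the members 10000 times. The use of that interval in reading the share was chosen after the shares were seen, and it was then required on both sides of 0.5 after glycolysis had first been read as explained by the trend.

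On simulated counts of 15381 genes with 200 changed, the test recovered 52.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, and 1.84% of the calls were unchanged genes. A list shifted by 0.2 was found (adjusted p = 6.57e-15, and adjusted p = 0.0225 with an estimated correlation), and 0 other lists were called. With no change simulated, 0 genes and 0 lists were called. The genes were simulated independently and without a GC or length trend, whereas the called lists had estimated correlations of 0.431 to 0.852. The changed genes were drawn from those with a mean of at least 1 CPM, and each gene was given the dispersion of the trend at its level. These results therefore hold for independent genes only, and the recovery does not cover genes at lower levels. In the real libraries, splits that mix the groups called up to 6 genes and 10 lists.

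Alternatives were RLE, upper quartile and no scaling factors, no filter and a strict filter (1 CPM in 3 libraries), protein-coding genes only, DESeq2 1.42.0, limma-voom, a replicate block, no robust estimation, PRDM16 left out of library sizes, limma on log2 FPKM with pseudocounts of 1 and 0.1, leaving out each library, an adjusted p under 0.01 and a test against 1.5-fold. Chosen after the data were seen were the removal of the length and GC trend, the sum over the places of each gene name, the restriction to genes listed once, and that restriction together with the removal of the trend. All 10 splits of the 6 libraries into 3 and 3 were refitted.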

Results

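Gene expression was measured by RNA sequencing in a human podocyte cell line, HPC, derived from the epithelial cell that wraps the filtering capillaries of the kidney. All cultures were kept in high glucose, a model of the diabetic kidney, and received either a negative control (NC) lentivirus or a lentivirus made to overexpress PRDM16. The titles give 24 h and do not say whether it counts from the glucose or from the lentivirus. PRDM16 is a zinc finger transcription factor best known for directing precursor cells into brown fat. There were 3 libraries in each of the 2 groups, and the labels do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The NC libraries held 22460881, 27655378 and 20969179 gene counts and the PRDM16 libraries 20147135, 28730146 and 41280350. No culture in normal glucose was analysed here, so every comparison is between the lentiviruses within high glucose.

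The question was which transcripts differed when PRDM16 was overexpressed. PRDM16 itself was absent from the NC libraries, with 0 counts in each, and was detected in every PRDM16 library, with 11, 18 and 24 counts. Its level with the PRDM16 lentivirus was 0.598 ± 0.0422 CPM (counts scaled to 1000000 per library; SD, n = 3), which pooled over the group was at least 13.9-fold higher than the 3 counts that the depth of the NC group allows. The gene passed the edgeR quasi-likelihood test (adjusted p = 7.7e-04) and in 19 of the 20 alternatives that gave it a value (adjusted p 6.5e-09 to 0.0674), and all 3 PRDM16 libraries lay above all 3 NC libraries, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. PRDM16 lies on chromosome 1 at 3069203 to 3438621 (hg38, plus strand). Its level stayed low: 6.27% of the tested genes had a lower mean in the PRDM16 libraries, where the median tested gene stood at 20.8 CPM. MECOM, the closest relative of PRDM16 in the same protein family, had 18.0 ± 3.68 CPM with NC and 15.4 ± 1.39 with PRDM16 (SD, n = 3), a log2 fold change of -0.22 ± 0.14 (SE) that did not pass (edgeR adjusted p = 0.391).

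Few other genes passed in edgeR. Of 15381 genes tested, 10 passed an adjusted p of 0.05, with 9 higher and 1 lower in the PRDM16 libraries, and 7 of these moved at least 2-fold. The balance of directions depended on single libraries, with 59 higher and 114 lower without NC library 3 and 3 higher and 6 lower without NC library 2. Besides PRDM16, the largest rises were in TCEA3-2, DECR2-2 and NFKBIB-2. These are second listings, on scaffolds or alternate haplotypes outside the chromosomes, of genes that also have a place on a chromosome. TCEA3 is a transcription elongation factor and DECR2 a peroxisomal enzyme of unsaturated fatty acid breakdown. NFKBIB is an inhibitor that holds NF-kappaB in the cytoplasm. At their places on the chromosomes these 3 genes had at most 1 count per library. How reads that match both places were assigned is not given, so the low counts there do not show that those places were silent. TCEA3-2 went from 0.415 ± 0.0664 CPM with NC to 6.27 ± 2.39 with PRDM16 (SD, n = 3; log2 fold change 3.91 ± 0.29 SE, edgeR adjusted p = 9.7e-08). DECR2-2 went from 1.38 ± 0.466 to 9.88 ± 2.30 CPM (2.84 ± 0.24, edgeR adjusted p = 1.3e-05) and NFKBIB-2 from 2.82 ± 1.13 to 14.9 ± 2.68 CPM (2.40 ± 0.25, edgeR adjusted p = 0.00641). The genes with the highest levels among the 10 rose less. TRAPPC5, a subunit of a vesicle tethering complex on chromosome 19, rose from 30.7 ± 2.88 to 48.5 ± 6.47 CPM (0.66 ± 0.13, edgeR adjusted p = 0.0462). MSRA-2, the scaffold listing of the methionine sulfoxide reductase MSRA, rose from 10.1 ± 1.48 to 16.7 ± 0.653 CPM (0.73 ± 0.14). With the 2 places of MSRA summed the change was 0.65 ± 0.27 and did not pass in edgeR. The serine hydrolase OVCA2 rose from 6.98 ± 0.699 to 12.1 ± 0.202 CPM. OVCA2 overlaps DPH1 on chromosome 17, so the reads of these genes cannot be fully separated.

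The other genes that passed had low counts and were named after their values were seen. VPS53, part of a complex that returns vesicles to the Golgi, rose from 1.91 ± 0.118 to 7.08 ± 3.03 CPM (SD, n = 3; log2 fold change 1.87 ± 0.26 SE). CKMT1B, a mitochondrial creatine kinase, rose from 1.31 ± 0.181 to 3.65 ± 1.24 CPM (1.49 ± 0.25). It has a near-identical copy, CKMT1A, so its count is uncertain on its own, and the sum of the pair went from 2.56 ± 0.579 to 5.11 ± 1.32 CPM. PADI4, an enzyme that turns arginine into citrulline in proteins, was the only gene that fell, from 1.46 ± 0.709 to 0.365 ± 0.0415 CPM (-2.0 ± 0.35, edgeR adjusted p = 0.0187). No lower gene met the level set for naming, and the 5 lower genes with the smallest p did not pass in edgeR with the settings used here or in limma-voom, while DESeq2 called LINC01963 and HYOU1. In edgeR each of them passed under at least 1 alternative: LINC01963, HYOU1, NIPA2 and HELLS with no count filter, and LINC01963, CBWD3 and HELLS without NC library 3. They were the non-coding RNA LINC01963 (log2 fold change -0.66 ± 0.15), the endoplasmic reticulum chaperone HYOU1 (-0.59 ± 0.13), the magnesium transporter NIPA2 (-0.76 ± 0.18, and -0.43 ± 0.15 with its 2 places summed), CBWD3, one of a family of near-identical copies (-0.67 ± 0.18), and the chromatin remodeller HELLS (-0.49 ± 0.13, and -0.30 without NC library 2).

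**Figure D1:**
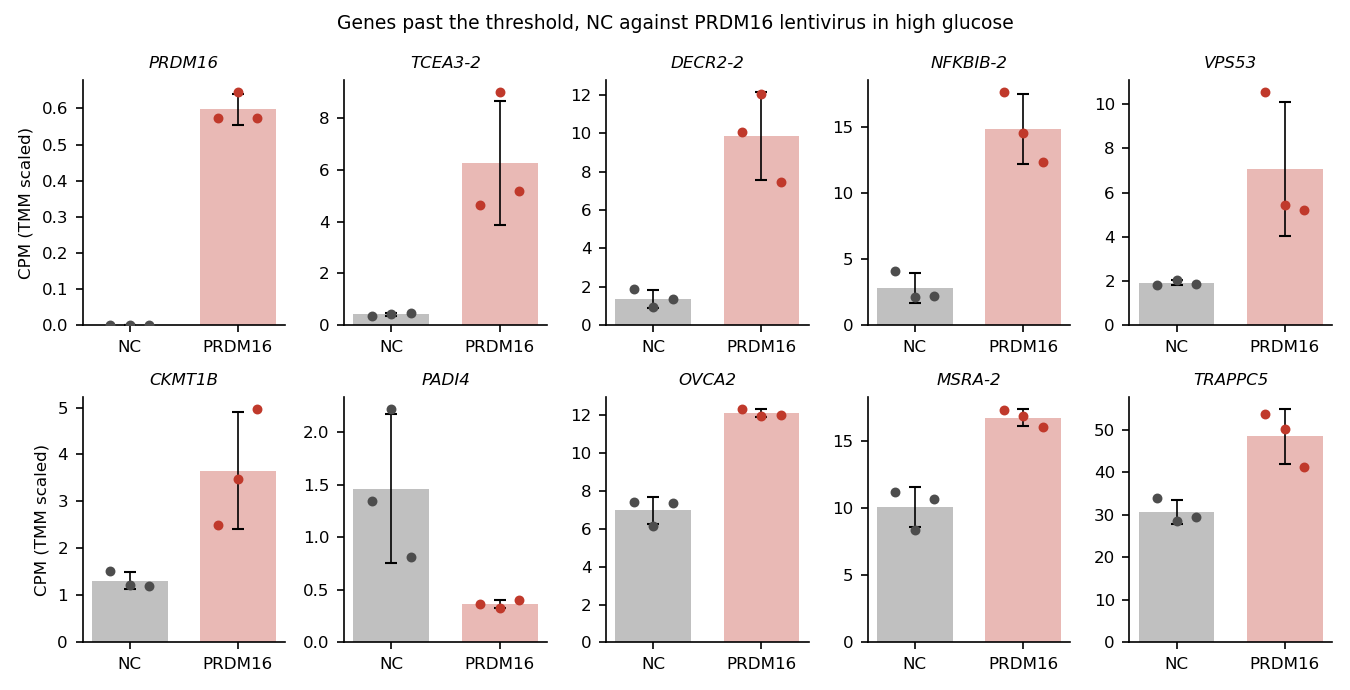
Level of each of the 10 genes that passed, in CPM scaled by TMM factors, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3). In each panel the PRDM16 libraries lie apart from the NC libraries, above them in 9 genes and below them in PADI4.

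Of the 10 genes, 6 (TCEA3-2, DECR2-2, NFKBIB-2, VPS53, MSRA-2 and PADI4) belong to genes that the files list at more than 1 place, on a chromosome and on a scaffold, against 995 of the 15381 tested (6.47%; Fisher's exact test, two-sided p = 1.21e-05). The number of genes depended on single libraries: 173 passed without NC library 3, 59 without PRDM16 library 2 and 20 without PRDM16 library 1. It was 48 with DESeq2 and 4 with limma-voom, against 10 in edgeR. At an unadjusted p under 0.05 there were 2459 genes, where chance gives 769, but the other 9 splits of these libraries into 3 and 3, each mixing the groups, gave 150 to 2092. The groups did not overlap in 3230 genes (21%, where chance gives 10%).

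Higher values were called in 3 lists: oxidative phosphorylation, cytosolic ribosomal proteins and glycolysis. Members of the oxidative phosphorylation list, the nuclear-encoded subunits of the respiratory chain, had a median log2 fold change of 0.19, with 47 of the 53 tested members higher with PRDM16. The cytosolic ribosomal proteins had a median of 0.18 (64 of 70 higher) and the glycolysis genes one of 0.19 (17 of 21 higher). With the length and GC trend described below removed, the medians of the 3 lists were 0.12, 0.095 and 0.080. These lists were called higher than other genes by camera with its preset correlation (adjusted p = 2.4e-07, 2.4e-07 and 0.00267). None held with the correlation estimated from the data (adjusted p = 0.796 with an estimated correlation for each), and the call of glycolysis was lost without NC library 1. No member passed in edgeR over all genes tested, although NDUFB7, NDUFA11 and ALDOA did with no count filter. At an unadjusted p under 0.05 there were 16 of 53, 14 of 70 and 4 of 21 members of the lists, all higher. Over all 15381 genes tested there were 2459, with 1419 higher and 1040 lower. DESeq2 called 2, 0 and 1 members, and limma-voom called 0 in each. Leaving out single libraries moved the medians of the lists to between 0.12 and 0.28, 0.11 and 0.30, and 0.14 and 0.26. The libraries overlapped, with the mean deviation of PRDM16 library 3 below that of NC library 3 in oxidative phosphorylation (-0.11 against 0.05) and the ribosomal proteins (-0.15 against 0.10).

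In the respiratory chain list 11 members passed when adjusted over the list alone, against 0 over all genes. The 4 with the smallest p were subunits of complex I, the entry point of electrons from NADH. NDUFB7 was at 76.1 ± 4.30 CPM with NC and 111 ± 11.5 with PRDM16 (SD, n = 3; log2 fold change 0.54 ± 0.11 SE), NDUFA11 at 171 ± 15.8 and 236 ± 19.1 CPM, NDUFS7 at 58.7 ± 7.04 and 79.6 ± 9.98 CPM, and NDUFS8 at 120.3 ± 13.4 and 161 ± 17.4 CPM. Of the glycolysis genes 2 passed when adjusted over the list alone, against 0 over all genes: the aldolase ALDOA, with 16.4 ± 2.25 and 25.04 ± 0.884 CPM (0.61 ± 0.13), and the lactate exporter SLC16A3, with 355 ± 19.8 and 459 ± 26.7 CPM (0.37 ± 0.12). ALDOA shares its span with a second annotated gene, so its count may hold only part of its reads. Of the ribosomal proteins 0 passed when adjusted over the list alone, and RPS28, with the smallest p, had 169.7 ± 17.8 and 225 ± 22.7 CPM (0.41 ± 0.12).

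The nuclear retained RNAs were lower. This list of long non-coding RNAs had a median log2 fold change of -0.43 over its 5 tested members, all of them lower with PRDM16 (camera adjusted p = 0.00444, and adjusted p = 0.796 with an estimated correlation). The list is named for retention in the nucleus, but the place of its members in the cell was not measured. TUG1 fell least (-0.23). Adjusted over the list alone, 3 passed, against 0 over all genes in edgeR and limma-voom and 1 in DESeq2. These were MALAT1, with 181 ± 48.0 CPM with NC and 119 ± 12.6 with PRDM16 (SD, n = 3; -0.61 ± 0.16 SE), NEAT1, the scaffold of paraspeckles, with 589 ± 104 and 436 ± 46.3 CPM (-0.43 ± 0.13), and KCNQ1OT1, with 8.94 ± 2.81 and 5.85 ± 0.828 CPM (-0.61 ± 0.20). Without NC library 2, which stood apart with a mean deviation of 0.54 over the list against -0.02 and 0.09 in the other NC libraries, the median was -0.27, with MALAT1 at -0.36, NEAT1 at -0.27 and KCNQ1OT1 at -0.32. With the length and GC trend described below removed, the median over all libraries was -0.25.

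Fold changes ran along the base composition and length of genes. Across the 13892 tested genes with a GC value, the log2 fold change correlated with GC content (Spearman's rho = 0.639), and across all tested genes it ran against length (rho = -0.392). Genes are not independent replicates, so no p is given. The trend was not particular to the real grouping, although the real split had the largest rho in size. In the other 9 splits, with NC library 1 always on the side compared against, rho with GC content ranged from -0.620 to 0.530. It was positive in each split with NC library 2 on the same side and negative in each of the others. Without NC library 2 the rho of the real groups was 0.441. With the trend removed the log2 fold change of OVCA2 went from 0.80 to 0.52, that of TRAPPC5 from 0.66 to 0.39, that of NDUFB7 from 0.54 to 0.20 and that of HES4 from 0.52 to 0.06. The median log2 fold change went from -0.21 in the lowest of 5 equal bins by GC content to 0.24 in the highest, and from 0.15 in the bin of the shortest genes to -0.17 in that of the longest. The members of the respiratory chain and ribosomal lists are short but have average GC content (means of 50.3% and 51.2%, against 50.8% over all genes with a value). The glycolysis genes are richer in GC (55.0%), and the nuclear RNAs are long and poor in GC (42.7%).

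**Figure D2:**
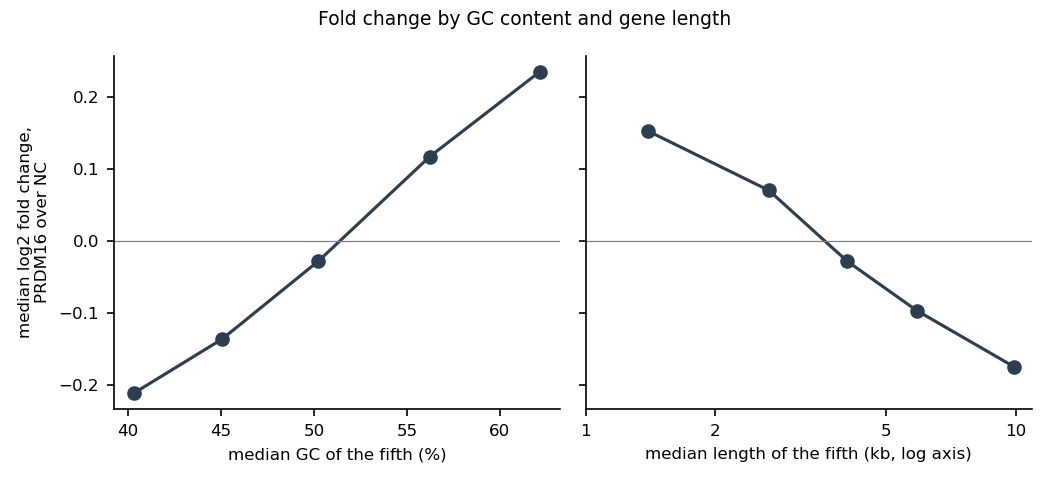
Median log2 fold change of PRDM16 over NC in 5 equal bins of the tested genes by GC content (left) and by gene length (right); each point is 1 bin. The median goes from -0.21 to 0.24 with rising GC content and from 0.15 to -0.17 with rising length.

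Genes of the podocyte itself were not called as a group. In the list of podocyte identity and slit diaphragm genes, the contacts that filter the blood, 18 of 27 members could be tested, 0 passed in edgeR, DESeq2 or limma-voom over all genes, 0 when adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.479). CD2AP, an adaptor of the slit diaphragm, had 206 ± 46.5 CPM with NC and 161 ± 16.1 with PRDM16 (SD, n = 3), and PLCE1, a phospholipase mutated in childhood nephrotic syndrome, 29.05 ± 3.61 and 23.5 ± 1.60 CPM. The log2 fold change of CD2AP, -0.35, was -0.15 without NC library 2. Among 25 adhesion and actin regulators of podocytes, 1 passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 0.587). This was PDLIM2, an actin-binding adaptor, with 58.6 ± 4.78 and 77.8 ± 3.19 CPM (log2 fold change 0.41 ± 0.11 SE). The extracellular matrix list (25 tested, camera adjusted p = 0.605) and the TGF-beta response list (21 tested, camera adjusted p = 0.658) had 0 members that passed in either count, with COL4A3, a basement membrane collagen, at 23.5 ± 4.03 and 18.0 ± 2.08 CPM (-0.39, and -0.23 without NC library 2), and TGFB1 at 45.0 ± 1.38 and 54.0 ± 2.86 CPM.

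The programme that PRDM16 drives in brown fat was not called either. Of its 26 listed genes 13 could be tested, 0 passed in edgeR, DESeq2 or limma-voom, 0 when adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.650). UCP1, the uncoupling protein that makes heat in brown fat, had between 2 and 4 counts in every library. The mitochondrial relative UCP2 was at 73.2 ± 6.33 CPM with NC and 86.9 ± 7.41 with PRDM16 (SD, n = 3), and PPARA, a nuclear receptor of fatty acid breakdown, at 21.02 ± 1.87 and 16.8 ± 0.825 CPM. In the fatty acid oxidation list 0 of 19 members passed in any of the 3 tools or over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.739). The same counts were 0 of 21 and 6 for mitochondrial biogenesis and dynamics (camera adjusted p = 0.959). POLRMT, the mitochondrial RNA polymerase, stood at 72.0 ± 1.42 and 89.7 ± 3.56 CPM and MFN1, a protein of mitochondrial fusion, at 39.6 ± 7.83 and 31.2 ± 2.49 CPM (-0.35, and -0.17 without NC library 2).

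Of the 45 lists fixed in advance, 43 had enough tested members, and the 39 not called had adjusted p between 0.119 and 0.975. The lowest belonged to the NADPH oxidases and antioxidant enzymes (17 tested, adjusted p = 0.119), where GPX1, a peroxide-clearing selenoprotein, was at 446 ± 47.7 CPM with NC and 590.0 ± 67.4 with PRDM16 (SD, n = 3). In the unfolded protein response list (camera adjusted p = 0.658) 1 member, HYOU1, passed when adjusted over the list alone, with 42.9 ± 6.22 and 28.4 ± 4.16 CPM, against 0 over all genes in edgeR and limma-voom, while DESeq2 called HYOU1. In the Notch pathway list (camera adjusted p = 0.658) 1 member passed when adjusted over the list alone, against 0 over all genes: HES4, a transcriptional repressor, with 108 ± 18.8 and 155 ± 19.2 CPM.

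**Figure D3:**
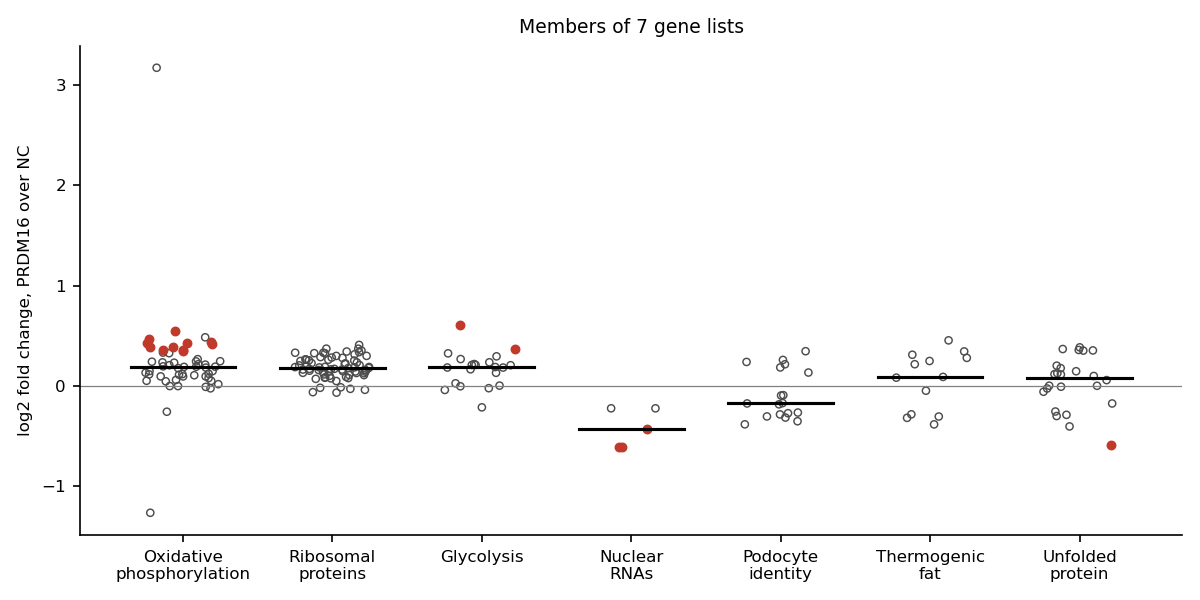
Log2 fold change of PRDM16 over NC for each tested member of 7 lists fixed in advance; filled points passed when adjusted over the list alone, open points did not, and bars mark the median. The bars lie at 0.19, 0.18 and 0.19 for oxidative phosphorylation, ribosomal proteins and glycolysis and at -0.43 for the nuclear RNAs.

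The libraries held a mixed profile of markers, given here over all 6 of them without a test between the groups. Some transcripts of the mature podocyte were near the floor: NPHS1, encoding nephrin, had 0 to 3 counts per library and the podocyte transcription factor WT1 between 1 and 4. Others were present, with PODXL at 117 ± 9.10 CPM, CD2AP at 185 ± 45.6 and SYNPO at 29.3 ± 1.5 (SD, n = 6). PAX8, a transcription factor of the developing and parietal kidney epithelium, was at 243 ± 21.1 CPM, and the epithelial keratins KRT8 and KRT18 at 1414 ± 134 and 677 ± 50.1 CPM, while the epithelial cadherin CDH1 was at 0.852 ± 0.214 CPM. Of other cell types, the endothelial PECAM1 had at most 0.0723 CPM, the leukocyte PTPRC 0.487 ± 0.0935 and the tubular LRP2 0 counts. PDGFRB, of the list of mesangial, pericyte and fibroblast markers, was at 24.5 ± 2.29 CPM, but 8 of the 13 members of that list could be tested and their list had a median of 3.23 CPM. From other lists, the matrix gene COL1A1 was at 303 ± 23.5 CPM and the mesenchymal gene VIM, which does not mark these cells alone, at 1364 ± 165.

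**Figure D4:**
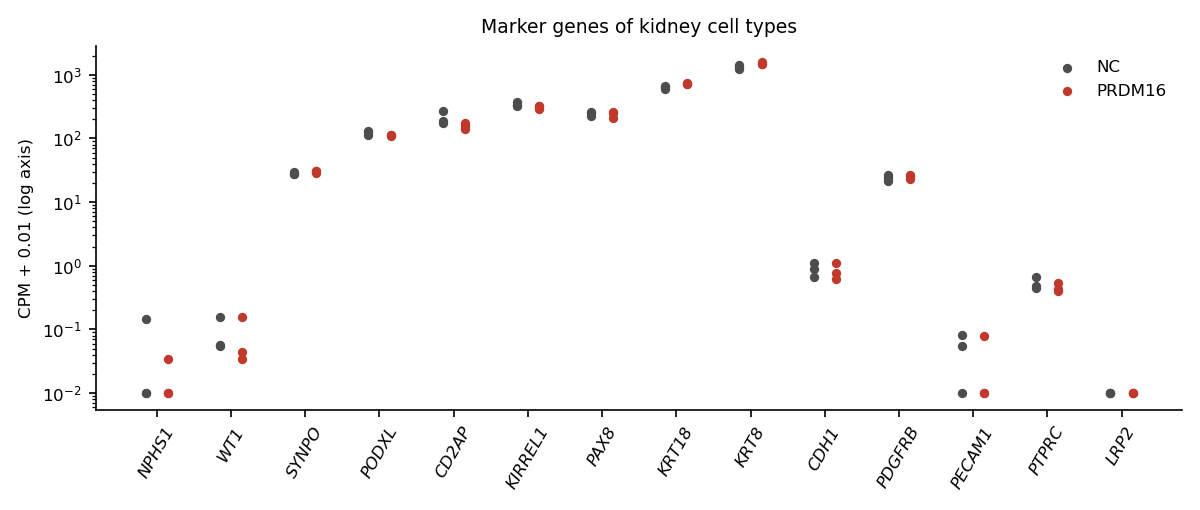
Level of 14 marker genes in each library, in CPM plus 0.01 on a log axis, with NC and PRDM16 libraries side by side. NPHS1 and WT1 lie near the floor in both groups, while PODXL, CD2AP, PAX8, KRT8 and KRT18 lie above 100 CPM.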

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

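The removal of the length and GC trend, the sum over the places of each gene, the restriction to genes listed once and its combination with the trend removal were chosen after the data were seen. PRDM16 passed in 19 of 20 alternatives that gave it a value (log2 fold change 4.88 to 7.12, adjusted p 6.5e-09 to 0.0674), and missed with the trend removed over genes listed once (6.97; with 0 counts in every NC library these fitted values depend on the tool and its prior count); the strict filter and the FPKM tests gave none. The count of 10 genes became 5 with library size only, 107 with no count filter, 48 with DESeq2, 4 with limma-voom, 4 without robust estimation, 3 with FPKM at either pseudocount, 6 at an adjusted p under 0.01, 5 with the trend removed, 18 with places summed, 48 over genes listed once and 0 over these with the trend removed (edgeR, with 942 at an unadjusted p under 0.05). The count of 7 genes changed at least 2-fold became 37, 15, 4, 4 and 3 with no filter, DESeq2, limma-voom, no robust estimation and FPKM, 4 with a test against 1.5-fold, 4 with the trend removed and 0 with it removed over genes listed once. Leaving out each library gave 7 to 173 genes, 7 to 53 at least 2-fold and 3 to 6 lists. The highest counts came without NC library 3; without PRDM16 library 2 there were 59 and 40 genes, without PRDM16 library 1 there were 20 and 19, and without PRDM16 library 3 there were 14 at least 2-fold. Both the stricter threshold and the 1.5-fold test ask for more by construction, and elsewhere the cause was not tested. With upper quartile factors 9 genes were higher and 4 lower, without NC library 3 there were 59 and 114, without NC library 2 there were 3 and 6, and without NC library 1 there were 4 and 3. NDUFB7, NDUFA11, ALDOA, MALAT1, HES4, LINC01963, HYOU1, NIPA2 and HELLS gained a call with no count filter, LINC01963 also with upper quartile factors, and CBWD3 over genes listed once. The 4 called lists became 0 with an estimated correlation and 0 with fry, and glycolysis was lost without NC library 1 and with the trend removed over genes listed once; elsewhere their medians kept their sign. SDF2L1 (-0.024) and JUNB (-0.047), which did not pass, changed sign with the trend removed, also over genes listed once (-0.012 and -0.044). The median degrees of freedom of the test went from 25.2 to 11.6 with the trend removed, and from 99.3 to 14.1 over genes listed once. The median SE went from 0.136 to 0.0952 and from 0.131 to 0.0906, and which of these changes bore on the calls was not tested.

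TCEA3-2 and DECR2-2 passed in 21 of 21 alternatives with a value and NFKBIB-2 in 20 of 21, VPS53 in 14 of 19, CKMT1B in 12 of 21, OVCA2 in 12 of 23, TRAPPC5 in 11 of 23, PADI4 in 10 of 18 and MSRA-2 in 8 of 21. Deviations of same-numbered libraries correlated at 0.0945, -0.104 and -0.131, which gave no sign that the numbers pair the samples. Library 1 of each group correlated best with its own number, but not every library did. Deviations from means of 3 libraries cannot exclude a pairing. With the replicate block 10 genes passed (6 higher, 4 lower), 5 of them shared with the fit without it, 10 changed at least 2-fold and 4 lists were called. No list test was run with DESeq2, limma-voom (whose list test is the main one) or without robust estimation. With 3 libraries per group at these depths, 1.5-fold changes were recovered in 52.2% of independently simulated genes with a mean of at least 1 CPM. Smaller changes are therefore mostly out of reach in such data, and genes at lower levels were not covered.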

Other observations

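The tests on genes listed at more than 1 place and on MECOM, the fits over genes listed once and the removal of the length and GC trend were chosen after the result was seen; the test on genes of the other splits was written before its own value but after the counts of those splits were known. When only genes listed once were tested, 48 passed in edgeR, 40 higher and 8 lower with PRDM16. The higher ones included TRAPPC5, the AP-1 subunit JUND (log2 fold change 0.56 ± 0.12 SE), the mitochondrial cholesterol carrier TSPO (0.53 ± 0.12), the secreted neurotrophic factor METRN (0.59 ± 0.13), the TWEAK receptor TNFRSF12A (0.52 ± 0.13), the creatine synthesis enzyme GAMT (0.48 ± 0.12), HES4 (0.53 ± 0.12) and NDUFB7 (0.55 ± 0.12). MALAT1 (-0.60 ± 0.13) and LINC01963 (-0.66 ± 0.14) were among the lower ones. These examples were picked after their values were seen. The 39 higher genes with a GC value had a median GC content of 65.0%, against 49.8% over the genes tested, and their median log2 fold change went from 0.56 to 0.25 with the length and GC trend removed over the genes listed once. None of the 45 called genes with a value then passed in edgeR, PRDM16 included, among 942 genes at an unadjusted p under 0.05. Fold changes became smaller, the median degrees of freedom of the test fell from 99.3 to 14.1, and the median SE of these genes fell from 0.131 to 0.0896. Which change in the fit ended the calls was not tested. JUND went to 0.17 ± 0.07, TNFRSF12A to 0.17 ± 0.08, HES4 to 0.08 ± 0.07 and MALAT1 to -0.34 ± 0.08, whereas LINC01963 (-0.57 ± 0.11) lost its call with little change in fold. For PRDM16, with 0 counts in every NC library, the fitted fold change is not a measured value and cannot show why its call ended.

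Some respiratory chain genes scattered between libraries of the same group. UQCRC2, a core subunit of complex III that the files list at more than 1 place, had 17, 37 and 13 counts in the NC libraries and 436, 35 and 53 in the PRDM16 libraries. NDUFS1, the largest subunit of complex I and also listed more than once, had 80, 945 and 377 counts with NC and 309, 96 and 161 with PRDM16. ACTN4, an actin crosslinker of podocyte foot processes that is abundant in most adherent cells, was at 1.26 ± 0.329 CPM (SD, n = 6) and is listed at more than 1 place as well.

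The first pattern is that genes listed at more than 1 place made up 6 of the 10 genes that passed, more than a lack of any link would give (Fisher's exact p = 1.21e-05). Reads moving from one place to the other would cancel in the sum, but the sum kept a median of 0.987 of the log2 fold change (0.888 to 1.001, with MSRA no longer passing). Except for MSRA, the other place held at most 3 counts in any library, so the counted reads did not move from there. Reads matching both places that were left out before counting would not show in this sum. A large shared shift of all such genes is excluded by their median of 0.095 (bootstrap interval 0.046 to 0.131). A small shared rise is not excluded, since the median over all tested genes was -0.024. In the other 9 splits of the libraries, each of which mixes the groups, 26 distinct genes passed and 92.31% of them were listed more than once (Fisher's exact p = 6.4e-27). A candidate explanation is therefore that the counts of such genes vary from library to library whatever the grouping, for example in how reads that match several places were assigned. A response to PRDM16 stays open for TCEA3-2, DECR2-2, NFKBIB-2, VPS53 and PADI4, which still passed in edgeR with their places summed. It is not excluded for MSRA-2 either.

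The second pattern is the shift of the called lists along the trend of GC content and length. The median of the nuclear retained RNAs lay at percentile 0 of 10000 matched lists. By the bound set before, this counts against the trend as its whole cause. However, the matched lists held shorter genes (mean log2 length 13.4 against 13.9). They also drew members independently, where the list had an estimated correlation of 0.852, so the percentile does not decide. The share of 0.574 kept with the trend removed decides nothing either (interval 0.0286 to 0.621). Oxidative phosphorylation (percentile 96.53, share kept 0.638), ribosomal proteins (82.36, 0.539) and glycolysis (94.45, 0.430) lay within the matched lists. They stayed called by camera after the removal (adjusted p = 2.5e-05, 0.00653 and 0.0293, but adjusted p = 0.972 with an estimated correlation), where the alternatives ranged from 1.2e-12, 3.2e-17 and 3.3e-05 to 0.796. By the bound set before, a share of at least 0.5 in a list still called, the first 2 of these would count against the trend. An interval, added after the shares were seen, leaves the trend and a response to PRDM16 as causes that cannot be told apart for all 3, since the intervals of the share kept (0.429 to 0.984, 0.259 to 0.777 and 0.302 to 0.728) all include 0.5. Differences between libraries whatever the grouping stay open too, since 7 of the 10 splits, the real one included, called at least as many lists. Mean deviations of oxidative phosphorylation and the ribosomal proteins were below 0 in NC libraries 1 and 2 and PRDM16 library 3. They were above 0 in the other libraries. These lists thus separated along the split that called 10 lists and not along the lentivirus. Glycolysis separated narrowly by lentivirus (0.028 in PRDM16 library 3, 0.024 in NC library 3).

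The third pattern is that PRDM16 counts were found in the PRDM16 libraries only, and at a low level. Reads of the relative MECOM counted as PRDM16 would keep the ratio of these genes alike in both groups, and it was not: each NC library held 0 PRDM16 counts beside 342 to 640 of MECOM, and each PRDM16 library 11 to 24 beside 292 to 707 (Fisher's exact p = 1.0e-15 on the pooled counts, which covers counting error only). This excludes MECOM reads as the source of the counts and says nothing about their level. The PRDM16 counts may miss part of the transgene, for example if its sequence was recoded or lacks the untranslated parts, which was not tested.

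The 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 10 genes and the highest other 6, for genes changed at least 2-fold 7 and 6, and for lists 4 and 10, so that 1, 1 and 7 of the splits gave as many, the real one included. The split with 10 lists set NC libraries 1 and 2 with PRDM16 library 3 against the others, which points to a structure of the libraries that the groups do not explain.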
